A study of Mus musculus with 39 samples.

How the data were processed

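The data were counts of polyA RNA reads per gene in 39 mouse libraries, made from 1000 sorted cells each (Vγ6 T cells and satellite cells) or from 2 ng of whole tibialis anterior RNA each. Per the labels, each condition stood for 2 to 3 independent biological replicates, and all the muscle had been injured with cardiotoxin. Wild-type and Tcrd-DTR mice of the time course and of the satellite cell experiment had been given diphtheria toxin, and the mice of the cytokine experiment were wild-type. The counts were deposited as raw counts per gene symbol, and STAR 2.7.3a, featureCounts, Subread 2.0.0 and the mm10 build are named per the submitters' processing notes. The library kit, the annotation, the strand setting and the handling of reads that map to several places or are duplicates are not given in the sources used here. Reads shared by near-identical genes or by overlapping and antisense genes may therefore be placed differently than assumed, and single values of such genes are uncertain.

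The table held 55011 gene symbols, all with a name, and every column matched the labels of 1 library. Libraries held 2372139 to 10974862 counts. The lowest chi-square per degree of freedom between 2 replicates of a group was 3.88, so no replicates of 1 group were copies of one another, and libraries of different groups were not compared in this way. Gene positions, and the length and GC content of each gene's longest transcript, came from the GENCODE annotation of the mm10 assembly (GRCm38), in which 52824 symbols had 1 position. PCR copies cannot be removed from these counts, so intervals and floors cover counting error only.

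Groups were taken from the labels. Differences between groups were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, the filterByExpr filter by group with a minimum count of 10 and a minimum total of 15), with Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. The Vγ6, cytokine and satellite cell comparisons were fitted on their own libraries, and the 4 days of the time course in 1 fit over 23 libraries, which share an estimate of the spread. Change over time, and the interaction of genotype with time, were F-tests over 3 coefficients. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one. The 39 lists of pathways and cell types held 582 symbols, of which 577 were found. Genes that changed over time in both genotypes were grouped by the day of their highest mean log2 CPM over the genotypes and tested with camera at each day. Genes that differed on depletion were tested as sets in the cytokine and satellite cell comparisons where a set had at least 10 tested genes. Single values were compared with exact permutation tests, 2-sided. Where a group had no counts the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact binomial 95% interval.

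The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest folds in each direction among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out names made of Gm and a number, ending in Rik or taken from an accession. It added up to 4 past-threshold members of each list with the smallest p, or the 2 with the smallest p where only the list passed, and the 10 smallest p of each test over time. The receptor genes, Il17a and Il17f were always taken, as were Pax7, Myod1, Myog, Myh3 and Col1a1 in muscle and satellite cells and Cxcl1, Csf3 and Lcn2 in the cytokine comparison. Genes named outside the rule are marked as chosen after their values were seen, and some genes taken by the rule are not reported here.

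The tests were checked on simulated counts with the real libraries' means and sizes, in which 100 genes were changed 2-fold and 100 changed 4-fold. In the Vγ6 comparison (11557 genes) 81 and 92 were recovered, with 11 false calls. With rIL-17A (12369 genes) 42 and 88 were recovered, with 12 false calls, and in satellite cells (11831 genes) 61 and 95, with 12. In the time course (17294 genes) 33 and 88 were recovered at day 1, 38 and 95 at day 3, 33 and 93 at day 7 and 51 and 94 at day 14, with 7, 10, 9 and 8 false calls. Of 395 genes simulated with an interaction 335 were recovered, with 35 false calls.

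Alternatives were DESeq2's size factors in edgeR, library size alone, no filter on low counts, DESeq2 1.42.0, each library left out in turn, the replicate number as a block, fits on 1 day alone or on all 27 whole-muscle libraries, estimated correlations, modules from wild-type means and sets of 200 genes. Chosen only after the data were seen were an offset that takes out each library's trend over transcript length and GC content, leaving out the 2 libraries with the most genes detected for their day, and a crossed pairing of the cytokine libraries. In 12278 genes simulated with a length trend for the cytokine comparison, the offset took the rank correlation of change with length from 0.677 to 0.022, the unchanged genes called from 791 to 8 and the 4-fold genes called from 95 to 88. No library was left out of the reported values. Splice forms and sequence variants were not analysed here, since the counts are per gene.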

Results

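RNA was sequenced from 39 mouse libraries in 14 groups. The first experiment held γδ T cells that carry the Vγ6 receptor chain, a lineage known for secreting interleukin 17A (IL-17A). They were sorted at 1000 cells per library from skeletal muscle 3 days after injury (n = 3) and from the colon of untreated wild-type animals (n = 3). The injury was made with cardiotoxin, a snake venom peptide that destroys muscle fibres and starts regeneration from satellite cells, the resident muscle stem cells. The second experiment followed whole tibialis anterior muscle (2 ng of RNA per library) at days 1, 3, 7 and 14 in wild-type (WT) and Tcrd-DTR mice. DTR mice carry the diphtheria toxin receptor in γδ T cells, so that the toxin, which both genotypes were given, removes these cells. Each group of this time course had n = 3 except DTR muscle at day 7 (n = 2). The third experiment compared whole muscle at day 7 of wild-type mice given recombinant IL-17A (rIL-17A, n = 2) or saline (PBS, n = 2). The fourth compared satellite cells sorted at day 1 from DTR and WT mice (n = 3 each). Total counts per library ran from 2372139, in DTR muscle at day 14, to 10974862, in DTR muscle at day 7. Here ± follows a log2 change as its standard error and a mean CPM (counts scaled to a common library total) as its SD, and adjusted p-values are those of edgeR's quasi-likelihood test for genes and of camera for gene lists. Where a list call was lost with the correlation between its genes estimated rather than preset, that adjusted p follows after "or". List counts adjusted over the list alone are given where they differ from those over all genes tested.

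Vγ6 cells of injured muscle and of colon were set against one another, the same lineage in 2 tissues. Only the muscle had been injured, so tissue, injury and the handling of each tissue cannot be told apart here. The muscle cells carried more of the genes that move lymphocytes through blood and lymph. S1pr1, the sphingosine 1-phosphate receptor that guides T cells out of tissue (chromosome 3, 115710433 to 115715072), was 18.3-fold higher in muscle cells (log2 change 4.20 ± 0.17, adjusted p = 6.91e-10, 361 ± 54.3 against 20.1 ± 5.77 CPM). Its relative S1pr4 was 4.28-fold higher and the integrin chain Itgb1 6.32-fold higher. Of 11 tested genes of circulation and muscle-directed trafficking, 7 rose and 2 fell, and the list stood apart from other genes (median log2 change 0.64, or 1.32 without colon replicate 1, adjusted p = 4.47e-07). Among the genes with the largest rises were the chemokine receptors Ccr6 (chromosome 17, 8236043 to 8257141; 15.1-fold, 239 ± 40.5 against 16.7 ± 11.3 CPM) and Ccr10 (20.5-fold), and Fut7, an enzyme that builds selectin ligands (13.3-fold). The transporter Slc22a4 had 89 counts in muscle cells and 1 in colon cells, a ratio of 81.8 (95% counting interval 14.3 to 3265).

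The residency and gut homing list split, with 4 of 10 tested genes higher and 5 lower in muscle cells (median −0.87, adjusted p = 0.000654, or adjusted p = 0.0699 with an estimated correlation). Itgae, the integrin chain that binds E-cadherin of epithelia (chromosome 11, 73090583 to 73147446), was 7.85-fold higher in the muscle cells (log2 change 2.97 ± 0.21, adjusted p = 3.55e-05, 1030 ± 99.6 against 132 ± 38.8 CPM). Itga1, the collagen-binding integrin chain of resident T cells, was 78.8-fold lower, and Cd69 (chromosome 6, 129267325 to 129275436) and Rgs1, which hold T cells in tissue, were 3.27-fold and 3.50-fold lower.

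The colon Vγ6 libraries carried the higher levels of cytotoxic and activation genes. Of 15 tested genes of the cytotoxic and type 1 program 12 fell and none rose in muscle cells (adjusted p = 1.31e-26). The median log2 change was −3.81, also with 2 members at the bound their counts allow. Fasl, the death ligand (chromosome 1, 161780689 to 161788495), was 288-fold lower (log2 change −8.17 ± 0.41, adjusted p = 3.13e-06, 1.05 ± 0.76 against 317 ± 103 CPM). Tbx21, the master transcription factor of type 1 lymphocytes (chromosome 11, 97098071 to 97115331), was 16.5-fold lower, Stat4 3.98-fold and the natural killer receptor Klrk1 2.41-fold lower. Ifng and Xcl1 had no counts in muscle cells against 72 and 99 in colon cells, at least 26.1-fold and 35.9-fold lower against a floor of 3 counts over the group. The natural killer genes Slamf7 and Klrb1c were 344-fold and 100-fold lower. Of 21 immediate early genes, which answer stimulation within minutes, 15 fell and none rose (16 and 1 adjusted over the list alone; median −1.70, adjusted p = 6.54e-27). Fos fell 5.67-fold (chromosome 12, 85473890 to 85477273; log2 change −2.50 ± 0.11, adjusted p = 7.76e-10, 787 ± 114 against 4460 ± 484 CPM), Fosb 4.04-fold, Dusp1 3.68-fold and Klf6 2.44-fold.

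**Figure D1:**
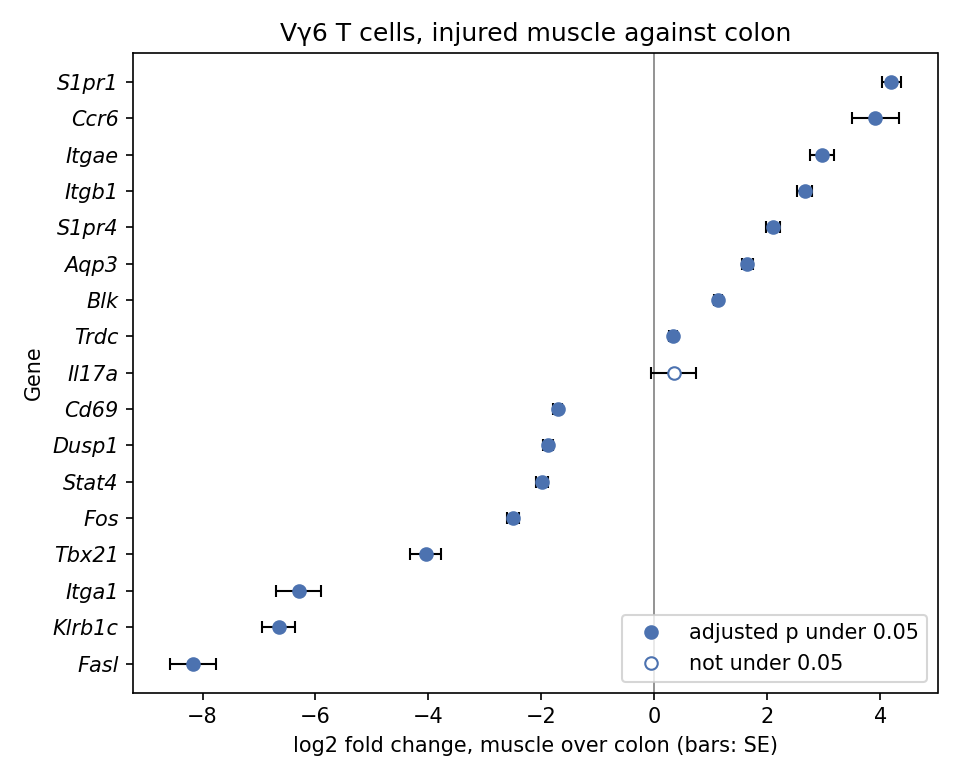
Log2 fold change of 17 named genes in Vγ6 cells of injured muscle over those of colon (horizontal axis, n = 3 per group), with the standard error as bars and filled points for an adjusted p under 0.05. S1pr1, Ccr6 and Itgae lie to the right of 0, Fos, Tbx21, Itga1 and Fasl to the left, and Il17a is the open point near 0, at 0.34.

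Several lists of inflammatory and regulatory genes were also lower in muscle cells. Of 8 genes of the IL-17 response list 7 fell (median −1.97, or −1.25 without muscle replicate 3, adjusted p = 6.08e-07, or adjusted p = 0.0699 with an estimated correlation). Among them were Ptgs2, the inducible prostaglandin synthase (15.4-fold), the chemokine Cxcl2 (6.87-fold) and the growth factor Csf2 (24.2-fold), all of which T cells can make themselves. Of 15 TNF and NF-κB targets 11 fell and 2 rose (adjusted p = 0.000163, or adjusted p = 0.342), Relb by 2.44-fold. Of 13 co-inhibitory and co-stimulatory receptors 8 fell and 3 rose (9 and 3 adjusted over the list alone; adjusted p = 2.61e-05, or adjusted p = 0.063), with Tnfrsf9 12.35-fold, Cd28 11.4-fold and Ctla4 5.39-fold lower. Of 7 regulatory T cell genes 4 fell (adjusted p = 0.000111, or adjusted p = 0.063), Il2ra by 2.11-fold. Of 18 ribosome biogenesis genes 10 fell (median −0.42, adjusted p = 0.000553, or adjusted p = 0.0876), Nop58 by 1.84-fold and Npm1 by 1.498-fold. Of 12 heat shock genes 5 fell (8 adjusted over the list alone; adjusted p = 0.000942, or adjusted p = 0.448), Hspb1 by 27.3-fold. Of 5 tested genes of fibro-adipogenic progenitors and fibroblasts 3 fell, Ly6a and Thy1, which T cells also express, by 4.87-fold and 1.35-fold (list adjusted p = 0.0211, or adjusted p = 0.161).

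The type 17 program, which defines these cells, did not move as a list: 8 of 18 genes rose and 4 fell (adjusted p = 0.0806). Aqp3, a water and glycerol channel, was 3.14-fold higher in muscle cells, the receptor chain Il17re 1.82-fold and the innate T cell factor Zbtb16 1.78-fold higher, and the aryl hydrocarbon receptor Ahr was 2.75-fold lower. Il17a itself (chromosome 1, 20730905 to 20734496) stood at 465 ± 40.1 CPM in muscle and 368 ± 196 CPM in colon cells (log2 change 0.34 ± 0.40, adjusted p = 0.614). Without colon replicate 1 it passed, at 0.86 (adjusted p = 7.5e-06). Il17f stood at 37.2 ± 16.9 against 79.3 ± 90.7 CPM (adjusted p = 0.518). Of 10 γδ T cell genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.000163, or adjusted p = 0.063 with an estimated correlation). The kinase Blk was 2.18-fold and the receptor δ constant gene Trdc (chromosome 14, 54142851 to 54148868) 1.25-fold higher. Trgc1, Trgc2 and Trgv6 were between 1.55-fold and 1.62-fold higher and Trgc4 1.31-fold lower, where reads shared between near-identical γ constant genes leave single values uncertain. Trgc3 stood at 5.50 ± 4.27 against 3.98 ± 2.87 CPM (adjusted p = 0.718).

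Among metabolic and repair genes, the lactate exporter Slc16a3 was 3.07-fold higher, the lipid droplet gene Plin2 1.91-fold and the fatty acid importer of mitochondria Cpt1a 1.90-fold higher in muscle cells, while Gapdh was 1.29-fold lower. Of 29 respiratory chain genes 4 rose and of 12 tissue repair factors 4 rose and 4 fell, with neither list past the test. Anxa1, Lgals1 and Lgals3, which are known to dampen inflammation or bind glycans, were 2.23-fold, 1.65-fold and 3.24-fold higher. Markers of other cells went both ways. Epcam of epithelia fell, at 5.33 ± 0.379 against 15.02 ± 3.74 CPM, and the myofibre gene Neb fell, at 5.12 ± 2.67 against 87.1 ± 24.3 CPM. The B cell receptor gene Cd79b rose 2.74-fold (134 ± 19.6 against 48.9 ± 5.25 CPM), in a list of 4 of which 2 rose and 2 fell (list adjusted p = 0.585). The endothelial gene Pecam1, which leukocytes also express, rose 1.865-fold (152 ± 6.06 against 81.3 ± 1.04 CPM), 1 of 4 tested endothelial genes (list adjusted p = 0.278). Of 4 tested general macrophage genes 2 rose, Lgals3 and Aif1, and none fell (list adjusted p = 0.318). Aif1 was 3.26-fold higher (8.01 ± 2.07 against 2.45 ± 0.890 CPM) and did not pass without colon replicate 2 (adjusted p = 0.056) or muscle replicate 2 (adjusted p = 0.0533) or 3 (adjusted p = 0.0576). The macrophage chemokine gene Ccl4, which cytotoxic lymphocytes also make, was 24.8-fold lower. In all, 2917 of 11907 tested genes differed, 1468 higher and 1449 lower in muscle cells. Of 64 list calls over all comparisons 3 held with an estimated correlation, all in this one: the cytotoxic program (adjusted p = 0.00888), the immediate early genes and the trafficking genes (adjusted p = 0.0488 each). Of 108 named genes that passed 89 did so under every setting tried.

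The depletion was checked first on the receptor genes it targets. Counts of 6 γδ receptor genes (Trdc, Trdv4, Trgc1, Trgc2, Trgc4 and Trgv6) summed to 129 in 12 WT muscle libraries and to 38 in 11 DTR libraries, of 65053654 and 60907367 counts in all. The mean difference within days was −1.499 CPM (exact permutation test within days, 2-sided p = 0.00499). At day 1 the sums were 15 counts in WT and 19 in DTR muscle (0.939 ± 0.262 and 1.36 ± 0.427 CPM, exact p = 0.3). At day 3 they were 64 and 10 counts (4.59 ± 0.626 and 0.733 ± 0.634 CPM), and at day 14 25 and 7 counts (2.30 ± 0.415 and 0.744 ± 0.568 CPM). Both days gave an exact p = 0.1, the smallest that 3 against 3 libraries allow. At day 7 they were 25 and 2 counts (1.09 ± 1.34 and 0.0911 ± 0.129 CPM, exact p = 0.5), with 20 of the 25 in WT replicate 3 (2.64 CPM) and 3 and 2 in the other WT libraries (0.427 and 0.215 CPM). The lower sum in DTR muscle at day 7 thus rested mostly on WT replicate 3, and a loss across libraries was not shown. Trdc alone had 14 counts in WT and 0 in DTR muscle at day 3, at least 5.14-fold lower, a bound that covers counting error only. It had 8 and 7 counts at day 1, 11 and 0 at day 7, 8 of the 11 in WT replicate 3, and 10 and 2 at day 14. Il17a had 0 to 3 counts per group throughout, too few to compare at this depth. Il17f had 6 counts in each genotype at day 1, 7 in WT and 12 in DTR muscle at day 3, 10 and 0 at day 7 and 14 and 8 at day 14 (exact p = 0.8, 0.9, 0.1 and 0.7). It had 0 counts in wild-type muscle at day 7 given PBS or rIL-17A.

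**Figure D2:**
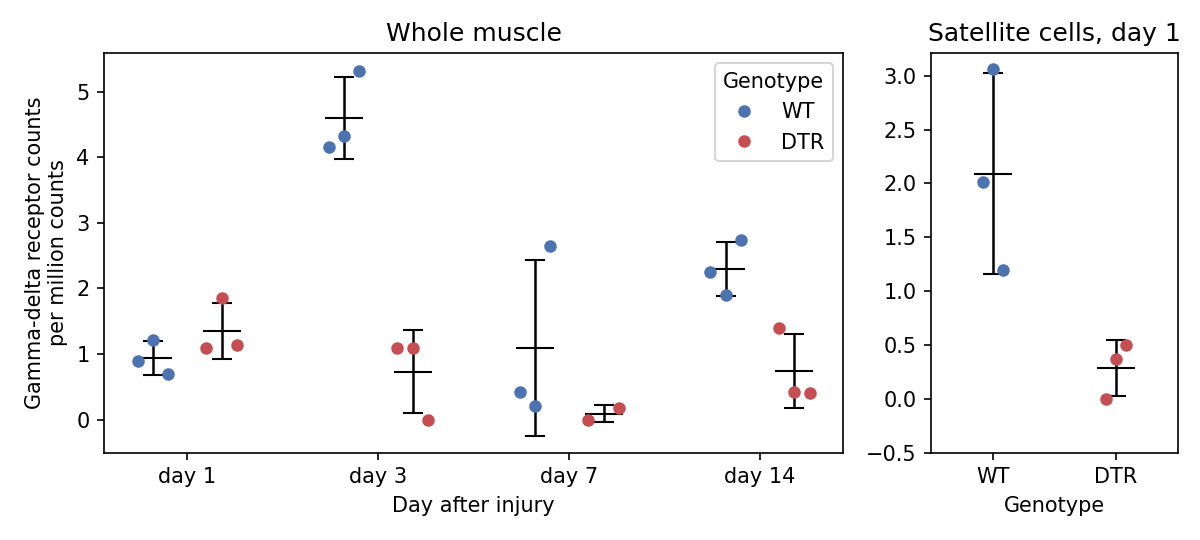
Counts of 6 γδ T cell receptor genes, in CPM, in whole muscle at days 1, 3, 7 and 14 (left) and in satellite cells at day 1 (right), each point 1 library of WT or DTR mice, with the mean as a bar and the SD as whiskers. At days 3 and 14 every WT library lies above every DTR library, and at day 1 the genotypes overlap.

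In injured WT muscle most genes of the IL-17 response list were highest at day 1, cell cycle and macrophage genes at day 3, and most genes of myoblast differentiation and of mature fibres at days 7 and 14. Of 18264 tested genes 9802 changed over the course in WT muscle and 10268 in DTR muscle, 7907 in both. Mt2, a metal-binding stress protein, fell from 294 ± 79.1 CPM at day 1 to 83.3 ± 13.5 at day 3, 9.88 ± 1.87 at day 7 and 4.015 ± 1.08 at day 14 (adjusted p = 3.74e-20). Atf3, Ppp1r15a, Hmox1, Osgin1 and Zfand2a, which are known to be induced by stress, the thrombin receptor gene Thbd, the cytokine receptor gene Tnfrsf12a and the fibre repair gene Xirp1 were among the 10 strongest and highest at day 1, with Hmox1 at 191.5 ± 16.1 CPM at day 1 and 183 ± 47.5 at day 3. Of 11 heat shock genes 6 peaked at day 1 in WT muscle and 3 in DTR muscle. In both genotypes all 28 cell cycle genes and all 10 general macrophage genes peaked at day 3. In WT muscle 16 of 21 IL-17 response genes and 8 of 15 neutrophil genes peaked at day 1, 15 of 20 genes of myoblast differentiation at day 7, and 16 of 23 mature myofibre genes at day 14. Myod1, the factor that commits satellite cells to muscle, stood at 113, 196, 66.35 and 49.1 CPM at days 1, 3, 7 and 14. Myog, which drives their differentiation, stood at 30.7, 302, 159 and 42.0 CPM and embryonic myosin Myh3 at 2.22, 37.7, 236 and 19.7. Fits with the replicate number within day as a block called 5489 genes in WT and 4420 in DTR muscle.

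At day 1 no single gene separated WT muscle from muscle labelled DTR, in which the γδ receptor genes were not lower (19 counts against 15). None of 18264 genes passed edgeR's test (777 at an unadjusted p under 0.05, DESeq2 also 0), and 2 passed with 2 libraries of unusually many detected genes left out, H2-Ab1 (−1.74) and Myom3 (1.63), named after their values were seen. In the preset test 9 lists passed, and none with an estimated correlation. Extracellular matrix genes lay lower in the muscle labelled DTR (median −0.39, 24 of 25 below 0, adjusted p = 2.22e-08, or adjusted p = 0.445). Col1a1 stood at 555 ± 192 against 876 ± 9.37 CPM and Col1a2 at 570 ± 190 against 908 ± 95.5. Repair macrophage genes, which mark the macrophages that clear debris and feed regeneration, lay lower too (median −0.38, adjusted p = 9.87e-06, or adjusted p = 0.387). Among them was the complement gene C1qa (53.0 ± 16.4 against 96.9 ± 10.7 CPM), which passed only with no filter on low counts (−0.96, adjusted p = 0.0215). So did cell cycle genes (−0.36, adjusted p = 1.03e-06, or adjusted p = 0.387) and general macrophage genes (−0.41, adjusted p = 0.000405, or adjusted p = 0.445). Genes of fibro-adipogenic progenitors (−0.35, adjusted p = 0.000768, or adjusted p = 0.455), of glycolysis (−0.26, adjusted p = 0.000596, or adjusted p = 0.387) and of mature myofibres (−0.23, adjusted p = 0.00663, or adjusted p = 0.797) lay lower as well. αβ T cell genes (2 tested) and erythrocyte genes lay higher, at 1.80 and 0.62 (adjusted p = 0.0481 and 0.0396, or adjusted p = 0.387 and 0.458). Every library labelled DTR lay above every WT library in counts of olfactory and vomeronasal genes (1687 ± 1034 against 667 ± 168 CPM), and over 7039 genes, which are not independent replicates, the log2 change correlated with GC content at Spearman rho −0.36. Without DTR replicate 1 the lists past the test numbered 5, and without DTR replicate 2, which held 2880 olfactory and vomeronasal CPM, they numbered 14. The matrix, repair macrophage and cell cycle lists kept their call with each library of the day left out. Mature myofibre genes turned to a median of 0.03 without DTR replicate 2 (adjusted p = 0.244) and did not pass without WT replicates 1 and 3 (adjusted p = 0.141 and 0.0706). General macrophage genes did not pass without WT replicate 2 or DTR replicates 1 and 3 (adjusted p = 0.116, 0.0577 and 0.0778), nor fibro-adipogenic genes without WT replicate 3 or DTR replicate 1 (adjusted p = 0.153 and 0.368) or glycolysis genes without DTR replicate 2 (adjusted p = 0.0741). αβ T cell genes did not pass without WT replicates 1 and 2 or DTR replicates 1 and 3 (adjusted p = 0.0696, 0.338, 0.055 and 0.182), nor erythrocyte genes without WT replicate 1 or DTR replicates 1 and 2 (adjusted p = 0.319, 0.303 and 0.0741). Of medians that still passed, that of matrix genes was −0.26 without DTR replicate 1, cell cycle genes −0.215 and −0.19 without WT replicate 2 and DTR replicate 1, and repair macrophage genes −0.60, −0.24 and −0.59 without WT replicates 1 and 2 and DTR replicate 2. General macrophage genes lay at −0.68 and −0.795 without WT replicate 1 and DTR replicate 2, mature myofibre genes at −0.38 and −0.43 without WT replicate 2 and DTR replicate 1, and αβ T cell genes at 3.61 without WT replicate 3.

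At day 3, interferon response genes lay lower in depleted muscle. All 22 had a negative change, with a median of −0.88 (adjusted p = 1.01e-20, or adjusted p = 0.0705 with an estimated correlation), and 10 fell when adjusted over the list alone. Rsad2, the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), stood at 41.0 ± 10.4 CPM in DTR and 83.7 ± 16.1 CPM in WT muscle (log2 change −1.03 ± 0.27, adjusted p = 0.437). Usp18, which trims the interferon-induced modifier ISG15, stood at 19.2 ± 3.44 and 41.2 ± 5.24 CPM. Genes of myoblast differentiation and fusion lay lower (median −0.58, adjusted p = 8.44e-08, or adjusted p = 0.13). The fusion genes Mymk and Mymx stood at 24.2 ± 4.49 against 46.6 ± 2.29 CPM and at 5.30 ± 1.25 against 12.9 ± 0.839 CPM. Satellite cell genes lay lower too (−0.22, adjusted p = 0.0105, or adjusted p = 0.113), with Myod1 at 138 ± 19.9 against 196 ± 11.5. Myog stood at 199 ± 63.2 against 302 ± 20.6 and Myh3 at 18.5 ± 9.27 against 37.7 ± 2.96 CPM. Adipocyte genes lay higher, all 8 above 0 with a median of 1.80, 4 of them rising adjusted over the list alone (adjusted p = 5.92e-11, or adjusted p = 0.0629). The adipocyte-secreted protease Cfd stood at 132 ± 40.6 against 25.4 ± 24.0 CPM. Mature myofibre genes lay higher (0.38, 22 of 23 above 0, adjusted p = 4.88e-10, or adjusted p = 0.41). So did those of fibro-adipogenic progenitors (0.25, 2 rose adjusted over the list alone, adjusted p = 0.000397, or adjusted p = 0.439), with Gsn at 1412 ± 381 against 601 ± 185 CPM. γδ T cell genes lay lower (−1.49 over 4 genes, adjusted p = 0.0103, or adjusted p = 0.113). The largest change was in the scavenger receptor gene Cd163l1 (chromosome 7, 140218267 to 140231145; 0.377 ± 0.403 against 5.34 ± 2.65 CPM), which passed with no filter on low counts (−3.84, adjusted p = 0.0307). Cell cycle genes (−0.24, adjusted p = 0.000397, or adjusted p = 0.432) and heat shock genes (−0.29, adjusted p = 0.00495, or adjusted p = 0.41) also lay lower. The interferon, myoblast differentiation and adipocyte lists kept their call with each library of the day left out. Without WT replicate 1 the mature myofibre genes had a median of 0.01 (adjusted p = 0.535) and did not pass, nor did cell cycle genes there or without DTR replicate 2 (adjusted p = 0.297 and 0.113). Satellite cell genes did not pass without WT replicate 2 or DTR replicate 2 (adjusted p = 0.0538 and 0.113), γδ T cell genes without WT replicate 2 or DTR replicate 1 (adjusted p = 0.134 and 0.0599), fibro-adipogenic genes without WT replicate 3 or DTR replicate 2 (adjusted p = 0.0653 and 0.089) and heat shock genes without DTR replicate 1 (adjusted p = 0.0599). Of medians that still passed, those without WT replicate 1 were 2.87 for adipocyte, 0.54 for fibro-adipogenic and −0.16 for heat shock genes, and without WT replicate 3 0.94 for mature myofibre and −0.18 for heat shock genes. Satellite cell genes lay at −0.36 without DTR replicate 1 and cell cycle genes at −0.38 without DTR replicate 3.

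No single gene passed edgeR's test at day 3 (873 of 18264 at an unadjusted p under 0.05). DESeq2 called 2, the potassium channel gene Kcnj12 (2.67) and the transcription factor gene Tbx15 (1.21), named after their values were seen, and the fit with a replicate block called 8. Without WT replicate 3 edgeR called 14 genes, all higher in DTR muscle, and without DTR replicate 1 it called Kcnj12 alone.

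**Figure D3:**
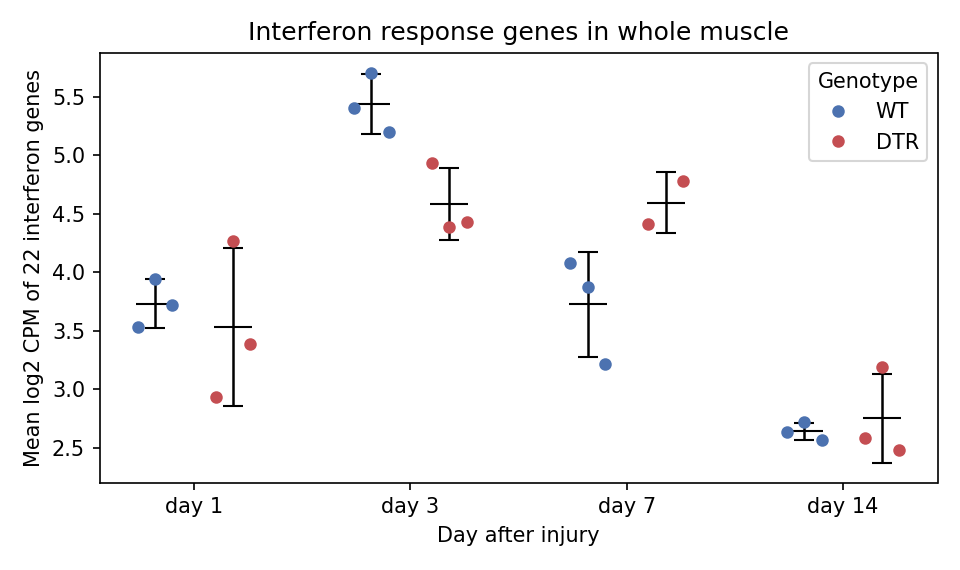
Mean log2 CPM of 22 interferon response genes in whole muscle at days 1, 3, 7 and 14 after injury, each point 1 library of WT or DTR mice, with the mean as a bar and the SD as whiskers. Every DTR library lies below every WT library at day 3 and above every WT library at day 7.

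At day 7, DTR muscle carried more of the genes of dividing cells. Mcm5, of the replication helicase (chromosome 8, 75109569 to 75128439), was 3.76-fold higher (log2 change 1.91 ± 0.35, adjusted p = 0.00222, 18.4 ± 4.99 against 4.95 ± 2.32 CPM). The mitotic cyclin Ccnb1 rose 3.17-fold and the proliferation marker Mki67 2.87-fold. Of 28 cell cycle genes 3 rose over all genes and 10 adjusted over the list alone, and 26 lay above 0 (median 0.55, or 0.83 without WT replicate 2, adjusted p = 2.27e-07, or adjusted p = 0.44 with an estimated correlation). Interferon response genes lay on the other side of WT than at day 3: 3 of 22 rose (10 adjusted over the list alone), 21 lay above 0 and the median was 0.87 (adjusted p = 8.08e-08, or adjusted p = 0.44). Ifih1 rose 2.62-fold, Rsad2 2.15-fold (49.6 ± 0.788 against 23.1 ± 3.15 CPM) and Oas1a 2.68-fold. The mean over the list in DTR minus WT muscle was −0.86 at day 3 and 0.87 at day 7. Neither day passed alone (exact permutation p = 0.1 and 0.2, smallest possible 0.1 each). The difference between the days of 1.73 had an exact permutation p = 0.01 over 200 relabellings within days.

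Single genes of other kinds also rose at day 7 in DTR muscle. Ms4a4c and Ms4a6c rose 8.49-fold and 4.58-fold and the chemokine gene Ccl12 (chromosome 11, 82101845 to 82103400) 6.51-fold. Of 17 genes of monocytes and inflammatory macrophages none rose and 1 fell, Nos2 (1 and 1 adjusted over the list alone), with a median of 0.34 and a test in the other direction (adjusted p = 0.955). The B cell receptor gene Cd79b rose 5.80-fold and insulin-like growth factor 1 (Igf1), a repair macrophage product, 1.99-fold. Matrix genes lay at a median of 0.71 (20 of 25 above 0, 9 rose adjusted over the list alone, adjusted p = 1.53e-05, or adjusted p = 0.689 with an estimated correlation). General macrophage genes (median 0.65, 3 rose adjusted over the list alone, adjusted p = 0.0207, or adjusted p = 0.692) and repair macrophage genes (0.28, adjusted p = 0.0334, or adjusted p = 0.749) lay higher over both DTR libraries. These 3 lists rested on DTR replicate 2, without which their medians turned to −0.04, −0.12 and −0.43, and without DTR replicate 1 they were 1.18, 1.18 and 0.82. The mean log2 CPM of the general macrophage genes was 4.99 in DTR replicate 1, below the 5.09 to 5.32 of the WT libraries, and 6.45 in DTR replicate 2. Both macrophage lists also did not pass without WT replicate 1 (adjusted p = 0.143 and 0.337). Higher were also genes of B cells (0.82, adjusted p = 0.0293, or adjusted p = 0.44) and endothelium (0.28, adjusted p = 0.0493, or adjusted p = 0.692). Heat shock genes (0.40, adjusted p = 0.0474, or adjusted p = 0.689) and respiratory chain genes (0.30, adjusted p = 0.00119, or adjusted p = 0.803) lay higher too. Of 14 genes of fibro-adipogenic progenitors 1 rose, the microfibril gene Mfap5 (2.385-fold; 4 rose adjusted over the list alone, list median 0.40, adjusted p = 0.0254, or adjusted p = 0.749). Of 20 myoblast differentiation genes 1 rose, the cell cycle inhibitor Cdkn1c (2.51-fold; 3 rose adjusted over the list alone, list median 0.52, adjusted p = 0.00119, or adjusted p = 0.498). Embryonic and neonatal myosin genes had a median of 1.24 (adjusted p = 0.0329, or adjusted p = 0.44). Myh3 stood at 505 ± 190 against 236 ± 111 CPM (adjusted p = 0.299) and Myh8 at 1620 ± 954 against 620 ± 328. Cd68, the macrophage lysosomal marker, stood at 93.4 ± 83.1 against 38.0 ± 6.34 CPM (adjusted p = 0.0634) and passed without DTR replicate 1 (log2 change 2.01), as did the immunoglobulin receptor gene Fcer1g (1.76). Pax7, the satellite cell factor, Myod1, Myog and Col1a1 had log2 changes of 0.71, 0.18, 0.11 and −0.25, none past the test. B cell genes did not pass without WT replicate 2 (adjusted p = 0.111) or either DTR library, nor endothelial genes without WT replicates 1 and 3 (adjusted p = 0.143 and 0.28) or DTR replicate 1. Heat shock genes did not pass without WT replicates 2 and 3 (adjusted p = 0.108 and 0.212) or DTR replicate 1, nor respiratory chain genes without WT replicate 3 (adjusted p = 0.073) or DTR replicate 1. Fibro-adipogenic genes did not pass without WT replicates 1 and 3 or DTR replicate 2 (adjusted p = 0.177, 0.103 and 0.457). Without WT replicate 3 and DTR replicate 2 in turn, neither myoblast differentiation genes (adjusted p = 0.0534 and 0.527) nor early myosins (adjusted p = 0.165 and 0.217) passed. Of medians that still passed, that of B cell genes was 2.26 without WT replicate 1, repair macrophage genes 0.64 and 0.45 without WT replicates 2 and 3, endothelial genes 0.435 and 0.52 without WT replicate 2 and DTR replicate 2, respiratory chain genes 0.48 without DTR replicate 2 and differentiation genes 0.93 without DTR replicate 1.

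Lower in DTR muscle at day 7 were Trim72, a membrane repair protein of muscle fibres (chromosome 7, 128003949 to 128011033; log2 change −3.76 ± 0.58, adjusted p = 0.000587, 0.926 ± 0.593 against 12.1 ± 10.2 CPM) and the autophagy gene Atg9a (7.10-fold). Lower too were the calcium channel gene Ryr2 (7.185-fold) and the glycerol kinase gene Gk (7.55-fold). Zbtb16 fell 4.675-fold and the triglyceride enzymes Dgat2 and Lipe fell 2.44-fold and 2.19-fold, while the fatty acid binder Fabp4 rose 1.92-fold. Of the immediate early genes Junb (chromosome 8, 84974484 to 84978718) fell 2.55-fold and Fos rose 2.86-fold. Nos2, the inducible nitric oxide synthase of inflammatory macrophages (chromosome 11, 78920787 to 78960254), had 3 counts in DTR and 47 in WT muscle, a ratio of 13.4 (interval 4.33 to 67.5). Olfr620 and Vmn2r53, of sensory receptor families with shared sequence, fell too and are uncertain, Vmn2r53 with 2 counts against 107 (ratio 45.91, interval 12.4 to 384). Counts of all such receptor genes were 731 ± 581 CPM in WT and 119 ± 38.3 in DTR muscle. Across 7039 genes, which are not independent replicates, the log2 change correlated with transcript length at Spearman rho −0.251. In all 117 genes were higher and 251 lower (955 in all with DESeq2). With library size alone as the scaling, which shifts the median of all genes by −0.23, 25 were higher and 583 lower, 4.11% higher against 31.8%.

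These day 7 calls rested on few libraries. Without DTR replicate 2 the count was 26, and 28 of the 31 named genes that had passed no longer did, with Mcm5, Atg9a and Gk the 3 that kept their call. Without WT replicate 3, which held 1383 olfactory and vomeronasal CPM, the count was 154 (Ifih1 at 1.17, adjusted p = 0.159), without WT replicate 1 729, and without DTR replicate 1 282 (Gk at −2.04, adjusted p = 0.153). The fit of day 7 alone called 92 genes, with Mcm5 at 1.79 (adjusted p = 0.0782), and the replicate block 137. Of the 31 named genes only Atg9a passed under every setting. Of 12 list calls those of the cell cycle and of the interferon response held with each library of the day left out. The list calls numbered 6 without WT replicate 3 and 7 each without DTR replicate 2, with the block and with a length and GC trend taken out.

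At day 14, 14 genes still separated depleted from WT muscle, 7 higher and 7 lower. Tnfrsf12a, the TWEAK receptor that muscle expresses after injury (chromosome 17, 23675445 to 23677468), was 4.57-fold higher in DTR muscle (log2 change 2.19 ± 0.26, adjusted p = 4.21e-06, 75.4 ± 22.9 against 16.5 ± 1.84 CPM). Cdkn1a, which takes myoblasts out of the cell cycle, rose 2.83-fold (139 ± 41.8 against 49.5 ± 6.23 CPM), Mt2 3.37-fold, the growth factor response gene Klf10 2.92-fold, the galectin gene Lgals3 of macrophages 2.58-fold, Junb 2.35-fold and Tmem176b 2.01-fold. Lower were Cactin, a splicing cofactor (chromosome 10, 81321103 to 81326242; 5.02-fold), the spermidine synthase gene Srm (chromosome 4, 148591503 to 148594993; 3.98-fold, 3.75 ± 1.19 against 14.5 ± 2.42 CPM) and the ribosome assembly gene Nop9 (2.76-fold). The acetyltransferase gene Kat2a fell 2.73-fold, the ubiquitin protease gene Usp48 2.57-fold, the peptide-processing gene Cpe 2.51-fold and the ubiquitin ligase gene Rnf10 2.445-fold.

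Genes of myoblast differentiation lay higher in DTR muscle at day 14 (median 0.74, 16 of 20 above 0, 1 rose and 7 adjusted over the list alone, adjusted p = 2.62e-12, or adjusted p = 0.139 with an estimated correlation). Myog stood at 112 ± 31.8 against 42.0 ± 4.93 CPM (log2 change 1.42 ± 0.35, adjusted p = 0.182) and passed with DESeq2 (adjusted p = 0.00538), with the replicate block (adjusted p = 0.021) and in the fit of day 14 alone. Cell cycle genes (0.47, 4 rose adjusted over the list alone, adjusted p = 1.7e-07, or adjusted p = 0.315) and general macrophage genes (0.61, or 0.265 without DTR replicate 2, 1 rose and 3 adjusted over the list alone, adjusted p = 7.31e-07, or adjusted p = 0.315) lay higher too. So did embryonic and neonatal myosins (1.07, adjusted p = 0.0164, or adjusted p = 0.315) and heat shock genes (0.28, adjusted p = 0.0365, or adjusted p = 0.694). Repair macrophage genes (0.23, or 0.39 without DTR replicate 1, adjusted p = 0.0365, or adjusted p = 0.728) and TNF and NF-κB targets (0.33, adjusted p = 0.0255, or adjusted p = 0.315) lay higher too. Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 53.5 ± 5.79 against 13.4 ± 3.16 CPM (adjusted p = 0.53, or 0.0474 with DESeq2 and 0.0368 with the replicate block). Myh3 stood at 47.0 ± 14.9 against 19.7 ± 1.27 (adjusted p = 0.872). The longest transcripts lay lower against the shortest in every DTR library than in any WT library at day 14 (long minus short median log2 CPM −0.818 ± 0.127 and −0.618 ± 0.0605, SD, n = 3 each). Over 7039 genes the change correlated with transcript length at rho −0.2, and the median length was 1648 bases for the 7 genes past the test that were higher and 3269 for the 7 lower in DTR muscle. Without DTR replicate 3 only Tnfrsf12a (2.04) and Cpe (−1.30) passed, without WT replicate 1 6 genes did and without DTR replicate 1 47. The differentiation, cell cycle and general macrophage lists kept their call with each library of the day left out. Heat shock genes did not pass without WT replicate 1 or DTR replicate 3 (adjusted p = 0.194 and 0.411), nor repair macrophage genes without WT replicates 2 and 3 or DTR replicate 2 (adjusted p = 0.171, 0.0573 and 0.243). Early myosins did not pass without WT replicate 2 or DTR replicate 3 (adjusted p = 0.0524 and 0.0698), nor TNF and NF-κB targets without WT replicate 2 or DTR replicates 1 and 2 (adjusted p = 0.0741, 0.0925 and 0.0527). DESeq2 called 66 genes, the replicate block 36 and the fit of day 14 alone 80, each including the same 14.

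The genes that changed over time in both genotypes were grouped by the day of their highest mean log2 CPM over the genotypes. The groups were then tested between genotypes in the same libraries, so a high DTR mean on a day favoured both membership and a rise. These p may thus be too small. At day 7 the 2507 genes peaking at day 7 and the 2659 peaking at day 3 lay higher in DTR muscle (median log2 change 0.34 and 0.27, camera adjusted p = 4.2e-17 and 4.04e-07), and the 1127 peaking at day 14 lower (−0.45, adjusted p = 3.64e-13). At day 3 the day 14 genes and the 1614 day 1 genes lay higher (0.18 and 0.04, adjusted p = 1.32e-08 and 0.021) and the day 3 genes lower (−0.12, adjusted p = 2.73e-06). At day 1 the day 1 genes and the day 3 genes lay lower in the muscle labelled DTR, whose receptor genes were not lower (−0.13 and −0.18, adjusted p = 2.19e-06 and 7.38e-12). At day 14 the day 14 genes lay lower (−0.09, adjusted p = 0.0335) and the day 3 genes higher (0.08, adjusted p = 0.0442). Of 16 such tests 10 passed and none did with an estimated correlation (smallest adjusted p = 0.306). A test of interaction, which asks whether the difference between genotypes changed with time, called 111 of 18264 genes. Junb lay lower in DTR muscle at day 7 (log2 change −1.35) and higher at day 14 (1.23; interaction adjusted p = 0.000717), and Srm went from 0.94 at day 7 to −1.99 at day 14. The count was 49 without WT replicate 3 of day 7 and 52 without WT replicate 2 of day 1. It was 58, 66 and 64 without WT replicates 1, 2 and 3 of day 14, 58 without DTR replicate 3 of day 14, 182 without WT replicate 1 of day 7 and 237 without DTR replicate 2 of day 1.

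Muscle given rIL-17A was compared with PBS muscle at day 7. Macrophage genes were lower. Cd68 (chromosome 11, 69664213 to 69666153) fell 5.75-fold (log2 change −2.52 ± 0.25, adjusted p = 3.39e-05, 23.1 ± 5.43 against 132 ± 13.5 CPM). The lysozyme gene Lyz2 fell 3.56-fold, the immunoglobulin receptor gene Fcer1g 3.39-fold and Lgals3 3.01-fold. Of 10 general macrophage genes 7 fell and none rose (median −1.68, adjusted p = 5.62e-06, or adjusted p = 0.995 with an estimated correlation). Of 18 repair macrophage genes 8 fell and 1 rose (median −0.86, adjusted p = 0.00472, or adjusted p = 0.995). The secreted matrix protein osteopontin, Spp1 (chromosome 5, 104435118 to 104441050), was 14.4-fold lower (log2 change −3.85 ± 0.37, adjusted p = 3.36e-05, 37.7 ± 4.57 against 544 ± 342 CPM), the lipid sensor gene Trem2 5.17-fold, Gpnmb 4.72-fold and the complement gene C1qb 3.13-fold lower. The matrix protease gene Mmp12 stood at 3.40 ± 1.33 against 95.8 ± 104 CPM and passed the test (log2 change −4.78, adjusted p = 0.00329). It did not pass without either rIL-17A library, at −5.33 without replicate 1 and −4.45 without replicate 3, nor with the replicate block or with no filter on low counts. The dipeptidase gene Dpep2 fell 21.5-fold.

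Genes of fibro-adipogenic progenitors and of the respiratory chain lay lower as well. Of 14 genes of fibro-adipogenic progenitors 6 fell and 1 rose (median −0.66, adjusted p = 0.0158, or adjusted p = 0.995 with an estimated correlation), the microfibril gene Mfap5 by 4.02-fold and the collagen-binding proteoglycans Lum and Dcn by 3.32-fold and 2.47-fold. The list median was −1.02 without rIL-17A replicate 3, and the list did not pass without PBS replicate 1 or rIL-17A replicate 1. Of 29 nuclear genes of the respiratory chain 19 fell (20 adjusted over the list alone; median −0.67, adjusted p = 2.53e-06, or adjusted p = 0.995). Cytochrome c (Cycs) fell 3.34-fold (132 ± 8.45 against 440 ± 2.91 CPM) and Sdhc 2.61-fold. Mitochondrially encoded genes took 4.07% ± 0.907 (SD) of counts with rIL-17A and 8.87% ± 0.529 with PBS. Of 24 matrix genes 9 fell and 2 rose, and the list did not pass (median −0.27, adjusted p = 0.335). Postn fell 3.18-fold and the collagen gene Col1a1 rose 1.96-fold (0.97 ± 0.23, adjusted p = 0.00723). Col1a1 turned to −0.15 with the trend over transcript length and GC content taken out and did not pass without rIL-17A replicate 3 (0.75) or with all 27 whole-muscle libraries in 1 fit.

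Genes of myoblast differentiation and both early myosins were lower with rIL-17A. Of 20 myoblast differentiation genes 11 fell and 2 rose (12 and 3 adjusted over the list alone; median −0.87, adjusted p = 0.00472, or adjusted p = 0.995 with an estimated correlation). Myf6 fell 3.34-fold, Cdkn1a 3.56-fold and the fetal troponin gene Tnnt2 3.31-fold, while the growth factor gene Igf2 rose 8.17-fold. Of the early myosins Myh8 fell by 2.74-fold (377 ± 66.7 against 1033 ± 31.8 CPM) and Myh3 by 1.95-fold, which did not pass with all 27 whole-muscle libraries in 1 fit. Their list (adjusted p = 0.0437, or adjusted p = 0.995) did not pass without PBS replicate 1 or rIL-17A replicate 1. Of 22 mature myofibre genes 9 rose and 5 fell, and the list did not pass (adjusted p = 0.254), with the calcium pump gene Atp2a1 4.95-fold, titin (Ttn) 4.60-fold and the calcium channel gene Cacna1s 4.25-fold higher. The intermediate filament gene Des rose 2.78-fold. Myog fell 2.025-fold (adjusted p = 0.0034), and stood at −0.64 (adjusted p = 0.0505) with the length and GC trend taken out. Myod1 fell 1.81-fold (adjusted p = 0.0129, 0.136 without rIL-17A replicate 3), and Pax7 stood at 2.96 ± 0.901 against 6.24 ± 2.41 CPM (adjusted p = 0.178, or 0.0372 with the length and GC trend taken out). Of 10 endothelial genes 5 rose and 1 fell, with the junction gene Cdh5 2.93-fold and the VEGF receptor gene Kdr 2.67-fold higher, and the list did not pass (adjusted p = 0.29). Their median of 0.535 was 0.16 with the length and GC trend taken out, where 2 of the 10 fell.

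Of 10 genes of the IL-17 response list that could be tested 1 rose and 3 fell (adjusted p = 0.29). The matrix protease gene Mmp3 fell 3.98-fold and the chemokine gene Ccl7 6.13-fold. Cebpd rose 12.3-fold (3.65 ± 0.999 against 0.270 ± 0.161 CPM), but not past the test without rIL-17A replicate 1 (3.84) or 3 (3.35). Cxcl1, Csf3 and Lcn2 had too few counts to be tested. Genes with the largest rises were nearly silent in PBS muscle: Anxa11 (chromosome 14, 25842156 to 25886804) stood at 95.7 ± 9.54 against 0.519 ± 0.371 CPM (log2 change 7.54 ± 0.41, adjusted p = 8.59e-07). Trim72 stood at 88.3 ± 2.13 against 0.739 ± 0.502. Nos2 had 166 counts against 1, a ratio of 221 (interval 39.1 to 8780), and Cnot3 232 against 2, a ratio of 154 (interval 42.3 to 1283). Prkcz2, Slc9a7 and Sema4c had no counts in PBS muscle and were at least 34.2-fold, 28.4-fold and 27.1-fold higher. Zbtb16 rose 62.7-fold, Slc16a3 6.85-fold, Gapdh 3.20-fold, Dgat2 5.37-fold, Acsl1 2.69-fold and the immediate early genes Ier2 and Nr4a1 8.43-fold and 4.00-fold, while Fos fell 4.84-fold. Trdc stood at 1.48 ± 0.756 against 1.16 ± 0.535 CPM (adjusted p = 0.802).

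In all 4400 of 12896 genes differed with rIL-17A, 2328 higher and 2072 lower. Long transcripts lay higher against short ones in these libraries: with genes in 4 classes of transcript length, the median log2 CPM of the longest class minus that of the shortest was −0.503 ± 0.222 with rIL-17A and −1.63 ± 0.0283 with PBS, and over 5945 genes the change correlated with transcript length at rho 0.464. With a length and GC trend taken out 3180 genes passed, 2656 of them among the 4400, and 57 of the 4400 had the other sign. Library size alone as the scaling, which shifts the median of all genes by 0.15, gave 63.5% higher calls against 52.9%. Without rIL-17A replicate 1 the count was 2371 and without replicate 3 2266. Of 107 named genes that passed 55 did so under every setting, and all those named above did except Col1a1, Myog, Myod1, Myh3, Mmp12 and Cebpd.

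**Figure D4:**
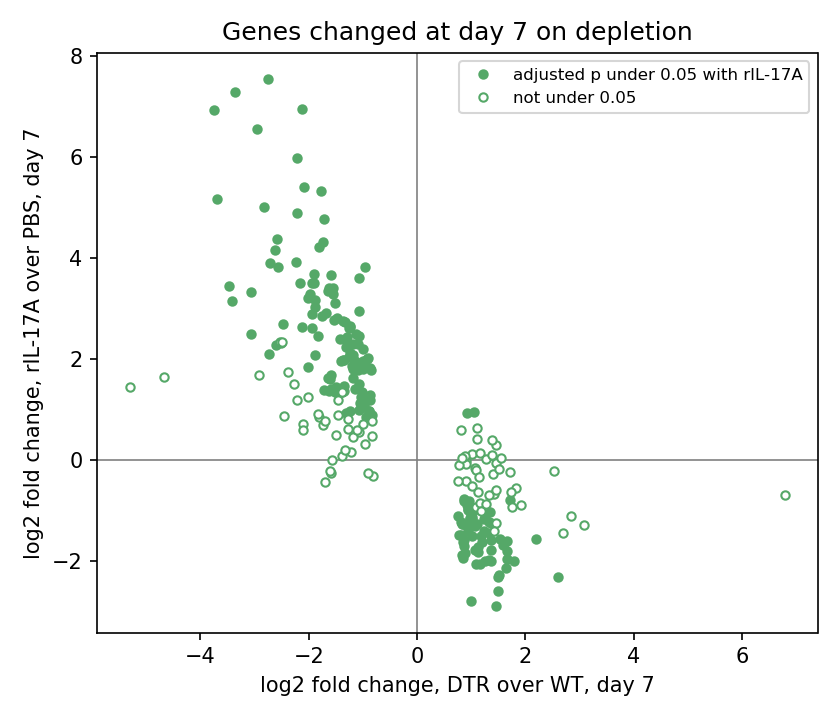
Log2 change with rIL-17A over PBS at day 7 (vertical axis) against the log2 change in DTR over WT muscle at day 7 (horizontal axis) for the genes that differed on depletion and could be tested in both, 117 higher and 163 lower in DTR muscle. Filled points passed with rIL-17A, and the median vertical value is −1.15 for the genes higher in DTR muscle and 1.87 for those lower.

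The genes that differed on depletion at day 7 were then followed in the rIL-17A experiment, which shares no library with the time course. The 117 genes higher in DTR muscle had a median log2 change of −1.15 with rIL-17A, and 71 of them fell and 2 rose (camera adjusted p = 8.89e-17, or adjusted p = 0.185 with an estimated correlation). Of the 251 genes lower in DTR muscle 163 could be tested, with a median of 1.87, and 125 rose and none fell (adjusted p = 1.1e-43, or adjusted p = 0.175). Trim72, Nos2, Zbtb16, Dgat2 and Lipe were lower in DTR muscle and higher with rIL-17A, and Mfap5 and Fos were higher in DTR muscle and lower with rIL-17A. The longest transcripts lay lower against the shortest in DTR than in WT muscle at day 7 (−1.499 ± 0.0898 and −1.22 ± 0.0842, SD, n = 2 and 3), the reverse of the order between rIL-17A and PBS muscle. Sets of the 200 genes with the smallest p in each direction gave the same directions at day 7 (−1.09 and 1.78). So did those of day 14 (−0.44 and 0.92, adjusted p = 1.01e-05 and 2.16e-13, or adjusted p = 0.18 each), a day at which the long minus short value also lay lower in DTR muscle. At day 3 both medians had the sign of the depletion, 0.73 for the genes higher in DTR muscle and −0.24 for those lower (adjusted p = 9.06e-06 and 0.0288, or adjusted p = 0.18 and 0.332). At day 1 the genes higher in the muscle labelled DTR had a median of 0.04 with rIL-17A and did not pass (adjusted p = 0.65), and those lower had a median of 0.365 (adjusted p = 0.0275, or adjusted p = 0.312).

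Satellite cells sorted at day 1 were compared between genotypes last. The receptor genes of γδ T cells had 33 counts in WT and 5 in DTR libraries (2.09 ± 0.934 and 0.288 ± 0.258 CPM, exact p = 0.1, the smallest possible), of which Trdc held 31 and 5, at traces far below the muscle genes. Interferon response genes lay higher in DTR cells (median 0.86, 14 of 15 above 0, 7 rose adjusted over the list alone, adjusted p = 3.51e-09, or adjusted p = 0.482 with an estimated correlation). The RNA sensors stood higher, Ifih1 at 14.2 ± 4.39 against 5.50 ± 1.95 CPM and Ddx58 at 22.4 ± 3.61 against 11.3 ± 1.94. Immediate early genes lay higher (0.44, 20 of 21 above 0, adjusted p = 1.61e-05, or adjusted p = 0.535). Cell cycle genes lay lower (−0.34, 27 of 28 below 0, adjusted p = 4.86e-10, or adjusted p = 0.535). The replication helicase genes Mcm7 and Mcm2 stood at 465 ± 27.3 against 603 ± 56.8 CPM and at 379 ± 40.9 against 491 ± 47.6. Satellite cell genes (−0.24, adjusted p = 0.000457, or adjusted p = 0.535), respiratory chain genes (−0.18, adjusted p = 0.000457, or adjusted p = 0.482) and glycolysis genes (−0.14, adjusted p = 0.0175, or adjusted p = 0.589) lay lower. The quiescence and activation lists did not pass (−0.06 and −0.01, adjusted p = 0.557 and 0.725). Genes of fibro-adipogenic progenitors (0.26, 4 rose adjusted over the list alone, adjusted p = 2.6e-05, or adjusted p = 0.267) and of matrix (0.14, adjusted p = 0.0111, or adjusted p = 0.589) lay higher. Pdgfrb stood at 48.5 ± 6.34 against 22.5 ± 5.51 CPM and Dpp4 at 19.8 ± 3.04 against 7.30 ± 2.24. Across 7391 genes, which are not independent replicates, the log2 change correlated with GC content at Spearman rho −0.451 and with transcript length at 0.205. Matrix genes did not pass without WT replicate 2 or DTR replicates 2 and 3 (adjusted p = 0.49, 0.163 and 0.356), nor glycolysis genes without WT replicate 3 or DTR replicate 2 (adjusted p = 0.632 and 0.092). Of medians that still passed, those without DTR replicate 1 were 0.535 for interferon, 0.08 for immediate early (adjusted p = 0.0486) and 0.26 for matrix genes, and without DTR replicate 3 −0.18 for cell cycle and 0.17 for fibro-adipogenic genes. Without WT replicate 3 they were −0.10 for satellite cell, −0.11 for respiratory chain, 0.45 for fibro-adipogenic and 0.25 for matrix genes, and without WT replicate 2 −0.36 for satellite cell genes.

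All 14 myofibre genes lay above 0 in DTR satellite cells (median 2.71, adjusted p = 2.6e-05, or adjusted p = 0.589 with an estimated correlation), which rested on DTR replicate 1, without which the median was −0.15 (adjusted p = 0.0711). Actin Acta1 stood at 541 ± 904 against 15.4 ± 1.26 CPM, and its log2 change of 5.13 was 0.27 without DTR replicate 1. Pax7 (27.6 ± 4.41 against 28.6 ± 8.09 CPM), Myod1 (3155 ± 240 against 3751 ± 630), Myog (3.28 ± 2.00 against 9.01 ± 8.01) and Col1a1 (2047 ± 269 against 1784 ± 478) did not pass. No gene of 12081 passed edgeR's test (719 at an unadjusted p under 0.05). DESeq2 called 11, all higher in DTR cells, among them Pdgfrb (adjusted p = 0.011) and Dpp4 (adjusted p = 0.0142). Without WT replicate 3, whose mitochondrial share was 0.257% against 0.731% to 0.858% in the other libraries, edgeR called Smoc2 (1.37) and Thbs1 (1.05), named after their values were seen. No day 1 muscle gene set was large enough to follow here. The 200 genes with the smallest p in each direction had medians of 0.19 for those higher in the muscle labelled DTR and −0.07 for those lower (adjusted p = 0.000451 and 0.00258, or adjusted p = 0.355 each).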

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

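The tests of the macrophage share of day 3 and of day 7 taken apart, and the removal of a trend over transcript length and GC content, were chosen only after the results were seen.

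The difference between genotypes changed with time in 111 genes. Those with the smallest adjusted p in edgeR's interaction test were Tnfrsf12a, Cpe, Prrc2a, Zbtb38 and Junb (0.000717 each), Srm and Rnf10 (0.00127 each), Lypla2 (0.0022), Gm4117 (0.00277) and Rab5b (0.00369). Tnfrsf12a, Cpe, Srm and Rnf10 were furthest apart at day 14, and Junb parted in opposite directions at days 7 and 14. The other 5 were lower in DTR muscle at day 7. Prrc2a stood at 3.33 ± 1.38 CPM in DTR (n = 2) and 20.03 ± 5.74 in WT muscle (n = 3) there, with a log2 change of −2.56 against −0.16 at day 14. Zbtb38 had a log2 change of −2.10, Lypla2 of −2.12, Gm4117 of −3.49 and Rab5b of −1.89 at day 7. Without DTR replicate 2 of day 7, Zbtb38, Lypla2, Gm4117 and Rab5b no longer passed the interaction test, while the other 6 genes passed with each library left out in turn.

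Interferon response genes lay lower in DTR muscle at day 3 and higher at day 7 (exact permutation p = 0.1 and 0.2). The difference between the days was 1.728 in the mean log2 CPM of 22 genes (exact permutation p = 0.01, smallest possible 0.005, unadjusted for choosing this list). A single library was argued against, since leaving out each library of either day kept at least 0.853 of that difference and turned no sign, and so was a trend over transcript length and GC content, whose removal kept 0.931. With the general macrophage score subtracted 0.623 of the difference stayed, and the days differed: at day 3 0.81 was kept (0.673 to 1.004 on leaving out each library), which argues against the macrophage share as the whole cause there. At day 7 0.438 was kept (−0.157 to 1.349), so that at day 7 a changed macrophage share and a changed interferon response cannot be told apart with 2 DTR libraries. The removal of γδ T cells stays open as an untested hypothesis for both days.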

How the results depend on the processing

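The length and GC trend taken out, the 2 libraries with the most genes detected left out (DTR replicate 2 of day 1 and WT replicate 3 of day 7) and the crossed pairing were chosen only after the results were seen. Of 5190 values of named genes under other settings 4785 kept their side of the threshold, 367 no longer passed and 37 newly passed. Direction was compared only for changes between 2 groups that passed in the reported fit or under the setting. Of those 1 changed sign, Col1a1 with rIL-17A (−0.15 with the length and GC trend taken out, against 0.97). Leaving out single libraries made up 225 of the 367. The Vγ6 count stayed between 2252 and 2997 under every setting. Where a result changed the cause was not tested, except that leaving libraries out makes the groups smaller.

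With no filter on low counts the genes past the threshold numbered 17 at day 1, 34 at day 3, 508 at day 7, 55 at day 14, 101 in satellite cells and 519 for the interaction, against 0, 0, 368, 14, 0 and 111. DESeq2 gave 2 at day 3, 955 at day 7, 66 at day 14, 11 in satellite cells and 580 for the interaction. Library size alone gave 1 at day 3 (Tbx15, named after its value was seen), 608 at day 7 and 211 for the interaction. At day 14 it gave 66.7% higher calls against 50%, and at day 1 it shifted the median of all genes by 0.14. Fits of 1 day alone gave 92 at day 7 and 80 at day 14. With the 2 libraries left out the counts were 2 at day 1, 2 at day 3 (Tbx15 and Timp4, named likewise), 214 at day 7, 27 at day 14 and 170 for the interaction, and 14 lists passed at day 1. With the length and GC trend taken out 3180 genes passed with rIL-17A, against 4400, and 7 lists at day 7, against 12.

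Leaving out each library in turn gave 0 to 14 genes at day 3, 26 to 729 at day 7, 2 to 47 at day 14, 2266 to 5266 with rIL-17A, 0 to 2 in satellite cells and 21 to 237 for the interaction. Time counts ran from 8996 to 10237 in WT and from 8874 to 10061 in DTR muscle. Lists past the test ran from 12 to 14 in Vγ6 cells, 5 to 14 at day 1, 7 to 10 at day 3, 6 to 10 at day 7, 4 (without WT replicate 2) to 11 (without WT replicate 3) at day 14, 4 to 9 with rIL-17A and 9 to 11 in satellite cells. Where this left a lone library in a group, at day 7 in DTR muscle and with rIL-17A or PBS, that library is assumed to vary like the other groups.

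With an estimated correlation 3 lists passed in Vγ6 cells and 0 in each other comparison, 0 of 16 module tests passed against 10, and 0 sets of depletion genes passed with rIL-17A against 2. Sets of 200 genes gave 7 of 8 past the test with rIL-17A, and 2 in satellite cells where no set was large enough before, or 0 there with an estimated correlation.

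Libraries of one number did not deviate together in every pair of any comparison with 3 pairs: the correlations of same-numbered deviations ran from −0.013 to 0.021 in Vγ6 cells, −0.021 to 0.341 at day 1, −0.005 to 0.049 at day 3, −0.023 to −0.006 at day 14 and −0.096 to 0.031 in satellite cells, and not every library correlated best with its own number. Day 7 had only 2 pairs (0.104 and 0.134). The replicate block gave 8 genes at day 3, 137 at day 7, 36 at day 14, 5489 and 4420 over time in WT and DTR muscle and 7 lists at day 7, and moved no other count of genes, lists or modules by over 1.5 times. Of 392 values of named genes 23 no longer passed with the block and 3 newly did. A call lost under the block is not a weaker effect, since the samples share only a number. With rIL-17A the correlation was −0.145, and the crossed pairing called 5147 genes.

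Depth limits the cytokine genes, since Il17a had 0 to 3 counts per muscle group. Simulated 2-fold changes were recovered for 33 to 51 of 100 genes in the time course and 81 in Vγ6 cells, which did not follow depth, with 33 recovered at day 7, the deepest day, and 51 at day 14. The median biological coefficient of variation was 0.303 in the time course and 0.175 in Vγ6 cells.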

Other observations

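The test of a lower share of all other cell types, and the removal of a trend over transcript length and GC content, were chosen only after the results were seen.

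Vγ6 cells of injured muscle and of colon also differed in genes of lists that did not pass. Of 19 interferon response genes 5 rose and 4 fell in muscle cells (7 and 6 adjusted over the list alone; list adjusted p = 0.633). The antiviral genes Mx1 and Bst2 were 4.74-fold and 2.01-fold higher and the guanylate-binding proteins Gbp3 and Gbp2 5.71-fold and 2.14-fold lower. Of 11 hypoxia response genes 2 rose, Mxi1 by 3.51-fold and the oxidase gene Ero1l by 2.10-fold, and 1 fell (list adjusted p = 0.278). The lipid importer gene Cd36 was 11.1-fold and the arginase gene Arg1 8.25-fold lower. Il1r2, the decoy receptor for interleukin 1, had 71 counts in muscle cells and 1 in colon cells, a ratio of 65.23 (95% counting interval 11.34 to 2612). Trac, the αβ receptor constant gene, was 1.92-fold higher.

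Muscle given rIL-17A also differed in genes of lists that did not pass. Of 28 cell cycle genes 4 fell and 2 rose (4 and 1 adjusted over the list alone; list adjusted p = 0.254), among them the survivin gene Birc5 of dividing cells, 2.89-fold lower. Of 22 interferon response genes 3 fell and 2 rose (3 and 1 adjusted over the list alone; adjusted p = 0.254), with Bst2 2.46-fold lower. Of 7 type 17 genes 3 rose (3, with 1 lower, adjusted over the list alone; adjusted p = 0.254), among them the signalling gene Stat3 2.41-fold. S100b, a calcium-binding protein gene of the Schwann cell list, had 1 count against 34, a ratio of 25.54 (interval 4.285 to 1038). S100b did not pass without rIL-17A replicate 1 or 3, nor with the length and GC trend taken out (adjusted p = 0.0536). Among satellite cell genes the laminin-binding integrin gene Itga7 was 2.44-fold higher (log2 change 1.29), and stood at 0.53 with the length and GC trend taken out (adjusted p = 0.0689). Neutrophil genes lay at a median of 0.68 at day 14 and −0.74 at day 7 in DTR against WT muscle, and passed on neither day (adjusted p = 0.0992 and 0.661). The median or the mean of a list differed in sign from its test in 33 of 203 list tests, none of them past the threshold.

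Genes lower in DTR muscle at day 7 were higher with rIL-17A, and genes higher there were lower, by a difference of medians of 3.02 (log2). A trend over transcript length and GC content was argued against as the whole cause, since the difference stayed at 2.527 with the trend taken out (2.04 to 3.14 on leaving out each library of the cytokine experiment, larger camera adjusted p of both sets 1.48e-14, or adjusted p = 0.197 and 0.194 with an estimated correlation). Background reads in WT replicate 3 of day 7 were argued against too, since genes called without that library, 22 higher and 132 lower, gave 2.6 (2.14 to 2.85). An axis of library quality could not be excluded: over 18 libraries of days 1, 3 and 14 the score of these genes followed the long minus short transcript index within groups at r = 0.431 (exact permutation p = 0.146, rho 0.428, exact p = 0.136, 1 relation computed), or 0.553 without the 2 farthest libraries. A dependence on IL-17A, which the cytokine experiment adds and of which depletion removes a cell source, stays open as an untested hypothesis.

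Macrophage genes were lower with rIL-17A, at a median of −1.68. With the length and GC trend taken out the median was −1.124 (−1.221 to −0.994 on leaving out each library), with 7 of 10 genes past the test before and after, so that part of the change may follow that trend. Endothelial genes lay 2.21 above macrophage genes (1.86 to 2.44), or 1.284 (0.965 to 1.539) with the trend taken out, and fibro-adipogenic genes 1.02 above, or 0.454 (0.206 to 0.532). The size of these gaps depends on the trend, so a lower share of all cells other than muscle stays open as a part of the change. The cytokine itself stays open too and was not tested apart from these.

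Other splits of the same libraries were counted where groups had 3 libraries. In Vγ6 cells the real split called 2917 genes and 12 lists and the highest other split 0 and 7, with 1 of 10 splits as large for genes and 1 for lists. At day 1 the real values were 0 genes, 9 lists and 2 modules and the highest others 8, 14 and 4, with 10, 8 and 9 of 10 splits as large. At day 3 they were 0, 9 and 3 against 0, 11 and 4, with 10, 4 and 8 splits as large, and at day 14 they were 14, 7 and 2 against 0, 9 and 2, with 1, 4 and 3. In satellite cells 0 genes, 9 lists and 2 sets of 200 muscle genes stood against 0, 11 and 2, with 10, 2 and 9 splits as large. These 10 splits are too few for a share under 0.05. For change over time in WT muscle 1 of 100 splits of the 12 libraries was as large as the real 9802, the real one itself (highest other 3802), so that chance is excluded there.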
